A study of Arabidopsis thaliana with 4 samples.

How the data were processed

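Total RNA from 4 samples of whole 5-week-old Arabidopsis plants, 2 wild type (La-er) and 2 ago4-1, was labelled with biotin and hybridised to ATH1 arrays, per the labels' protocols. The deposited values are intensity values, one signal per probe set and array on a linear scale, made with GCOS per the submitters' processing notes. The version and settings of GCOS are not given in the sources used here. Each array had a trimmed mean of 500.1, so the deposited intensities were taken to be scaled array by array, and no further normalization was applied. The median signal ranged from 151 to 165.1 and the highest from 42660 to 45190. No detection calls were used, and signals were not compared between probe sets. No pair of arrays held identical values (0 pairs). Every column of values was matched to a sample by its name.

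The table held 22810 probe sets, of which 64 controls were left out. In the platform's annotation 13513 probe sets had 1 gene symbol, 503 had several and were not named, and 8730 were not listed and are unnamed here. Of those with 1 symbol, 13436 were matched by gene ID to RefSeq's gene table of the assembly TAIR10.1, which was used only for names and for which genes neighbour each other, since the files name no genome build. Genes known by a name were paired less often than genes known by a locus tag alone, at 14.1% and 63.1% of nuclear protein-coding genes. Of 415 genes on the lists, 50 had a named probe set, and AGO4 had 0.

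Values were transformed as log2(signal + 16). Probe sets with a mean log2 value under the 30th percentile over all 4 arrays were left out, leaving 15922. The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom and a median of 6.72 prior degrees of freedom. Differences are ago4-1 minus wild type, and a fold is on the log2(signal + 16) scale. Gene lists were tested with camera at a preset correlation of 0.01, for lists with at least 3 tested members, a minimum set after the data had been obtained, and with an estimated correlation and fry beside it. One probe set was used per locus, the one with the highest mean.

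The lists were RNA-directed DNA methylation; maintenance methylation, histone marks and demethylation; microRNA and post-transcriptional silencing; genes silenced by DNA methylation; flowering time; floral organ identity; anther, tapetum and pollen; seed and silique; photosynthesis and leaf; root. The others covered senescence, salicylic acid defence, jasmonate and wounding, cold, drought and abscisic acid, heat shock, cell cycle, meristem and leaf development, circadian clock, phosphate and iron deficiency, auxin and gibberellin, flavonoids and anthocyanins, and glucosinolate synthesis. The lists, the test, the naming rule and the alternatives, except those said to be added, were fixed before the data were examined. The 24 families, by symbol, biotype or chromosome, and the 35 late-pollen loci were added later, and the late-pollen loci were also tested with no low-signal filter. Named genes were the 12 with the largest increase and the 12 with the largest decrease among those past the threshold, paired with 1 gene and with both ago4-1 arrays on the same side of both wild-type arrays, and up to 4 members of each list with the smallest p. The same rule of 4 was used for the families, and genes of other sets were chosen after their values were seen.

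Calls near AGO4, taken as loci within 1000 steps of its locus number, and calls by chromosome were compared with Fisher's exact test. Windows of 51 neighbouring genes were compared with 10000 permutations of the calls, and windows about 3 times as wide were tried after the profile was seen. Intervals are 95% intervals, from 2000 bootstrap draws of genes, not of arrays, for medians and spreads. The procedure was tested on simulated data with 15922 probe sets and 2 arrays per group, of which 200 probe sets were changed. It recovered 40.6% of changes of 1 log2 unit and 85.2% of changes of 2 units, and 6.77% of its calls were unchanged probe sets. Camera found 100% of 5-gene sets shifted by 1 log2 unit and 0% of unshifted sets, and the window scan found 0 segments among evenly placed calls and 1 where 1 was planted. The simulated probe sets varied independently, so these rates do not cover sets or neighbours whose genes vary together.

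Alternatives were quantile normalization, arrays centred on their medians, pseudocounts of 1 and 64, no low-signal filter or one at the 50th percentile, no variance trend, robust moderation, a minimum difference of 1.2-fold, an adjusted p under 0.10, the replicate number as a block, and each array left out in turn. With 1 array left in a group, that array is assumed to vary like the other group's. Transposable element genes were not analysed here, since no table gave gene descriptions.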

Results

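Whole Arabidopsis thaliana plants, 5 weeks old and grown in hydroponics under long days, were profiled on Affymetrix ATH1 arrays, on which a set of short probes reports the transcript of a gene. The samples were 2 wild-type arrays, from the La-er line as the labels name it, and 2 arrays of ago4-1, a mutant of AGO4. AGO4 is the Argonaute protein that binds small interfering RNAs and directs DNA methylation. The titles call the arrays of a genotype biological replicates, so the p-values rest on the spread between these samples. For each gene that spread is moderated toward probe sets of similar signal (2 residual and a median of 6.72 prior degrees of freedom). The number of arrays limits the precision of the p-values. The median signal was 162.1 and 165.1 on the wild-type arrays and 151 and 164 on the ago4-1 arrays, with the same trimmed mean of 500.1 on each. Over the tested probe sets the log2 signals of the wild-type arrays correlated at r = 0.978 across genes, those of the ago4-1 arrays at 0.973, and arrays of different genotype at 0.949 to 0.96. The ratio of 3' to 5' signal of the GAPDH control was 1.56 and 2.05 in wild type and 1.41 and 1.74 in ago4-1, and that of the actin control was higher, at 8.25 and 11.27 in wild type and 8.78 and 7.99 in ago4-1. For both controls the genotypes overlapped. The signal of AGO4 itself is not analysed here, because no probe set was paired with its name.

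The comparison asks which transcripts differ between ago4-1 and wild-type plants, a question the submitters tie to the part AGO4 plays in plant development. Transcripts of pectin-modifying enzymes and of a cysteine-rich peptide were among those with the largest increases in ago4-1. The signal of the cysteine-rich peptide gene LCR66 was 85.1 ± 11.8 (SD, n = 2) in wild type and 1250 ± 115 (SD, n = 2) in ago4-1, a 12.6-fold rise. GILT, which encodes a thiol reductase, rose 13.3-fold, from 36.4 ± 0.459 to 679 ± 36.5 (SD, n = 2 each). In the other direction, AT3G47250 was 22.5-fold lower in ago4-1, at 16.4 ± 4.52 against 718 ± 166 (SD, n = 2 each). That fold is of signal + 16, and the log2 difference ran from -5.375 to -3.266 across the alternatives. CHX20, a cation exchanger of guard cells, was 4.66-fold lower, at 52.5 ± 3.12 against 307 ± 72.4 (SD, n = 2 each).

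Of 15922 tested probe sets, 647 differed at an adjusted p under 0.05 in limma's moderated test with Benjamini-Hochberg adjustment, 341 higher and 306 lower in ago4-1. Of these, 330 were paired with a single gene, 186 higher and 144 lower, and 374 differed by at least 2-fold. At an unadjusted p under 0.05 there were 3249. Without a fold test, 268 probe sets lay at least 2-fold apart in the same direction in all 4 pairs of arrays, 186 higher and 82 lower. Both ago4-1 arrays lay on one side of both wild-type arrays for 8340 probe sets, where chance gives 33.3% of those tested. The count of 647 moved to 280 without ago4-1 replicate 1 and to 1046 without ago4-1 replicate 2, and it was 140 with no low-signal filter and 93 with no variance trend. The balance of directions moved too, from 52.7% higher to 35.4% without ago4-1 replicate 2 (370 higher, 676 lower), 63.1% without wild type replicate 2, 62.4% without wild type replicate 1, 65% with no low-signal filter and 71% with no variance trend.

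Among the 12 named genes with the largest increases were 4 known for their expression in pollen. AT1G10770, a pectin methylesterase inhibitor, rose from 6.23 ± 1.53 to 342 ± 7.32 (log2 difference 4.01, SE 0.31, limma adjusted p = 0.000633). The pectin methylesterase AT5G07430 rose by 3.81 on the log2 scale, from 1.78 ± 0.350 to 236 ± 45.2. The polygalacturonase AT3G07820 rose by 3.43, from 17.44 ± 0.580 to 345 ± 20.2, and AT3G01240 rose by 3.56, from 3.24 ± 0.657 to 211 ± 20.4. AT1G54020, a GDSL-type lipase, rose 12.5-fold, and AT1G65870, of the dirigent family, rose 7.46-fold. AT3G02480, of the late embryogenesis abundant kind, rose 10.8-fold, from 9.42 ± 7.39 to 258 ± 76.4. OSM34, an osmotin-like protein gene, went from 28.2 ± 29.8 to 538 ± 466, AT1G33055 from 32.6 ± 27.1 to 341 ± 160, and AT1G47400, which encodes a peptide of the iron deficiency response, from 193 ± 67.4 to 1687 ± 1074 (SD, n = 2 each). Several of the wild-type signals were near the floor of the scale. Folds here are of signal + 16, which understates the change of low genes.

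Of the 12 named genes with the largest decreases, AT1G63540 fell from 185 ± 17.5 to 3.43 ± 1.26 (log2 difference -3.37, SE 0.39, limma adjusted p = 0.00372). AT2G33850 fell from 1976 ± 216 to 347 ± 4.72, a log2 difference of -2.45, and AT1G63980 fell from 1656 ± 91.0 to 292 ± 44.3, also -2.45. AT3G28220 fell from 2418 ± 355 to 592 ± 74.9, and AT1G59710 fell 5.25-fold, from 260 ± 51.7 to 36.7 ± 11.5. AT1G64380, of the ERF family of transcription factors, fell 3.82-fold. The other members were AT5G20460 at -2.51, AT3G46110 at -2.12, AT1G53450 at -1.92 and AT3G49160, of the pyruvate kinase family, at -1.81. Of these 24 named genes, 14 passed in each setting in which they were tested, 10 to 13 settings a gene since some settings filter a gene out, and 19 passed with any single array left out. Without ago4-1 replicate 1 the calls of AT5G07430, AT3G01240 and AT5G20460 were lost, without ago4-1 replicate 2 those of OSM34 and AT1G33055, and without wild type replicate 1 that of AT5G20460. Of the probe sets unnamed here, the 2 with the largest increases rose by 6.07 and 4.41 on the log2 scale, and the 2 with the largest decreases fell by 5.22 and fell by 2.79.

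**Figure D1:**
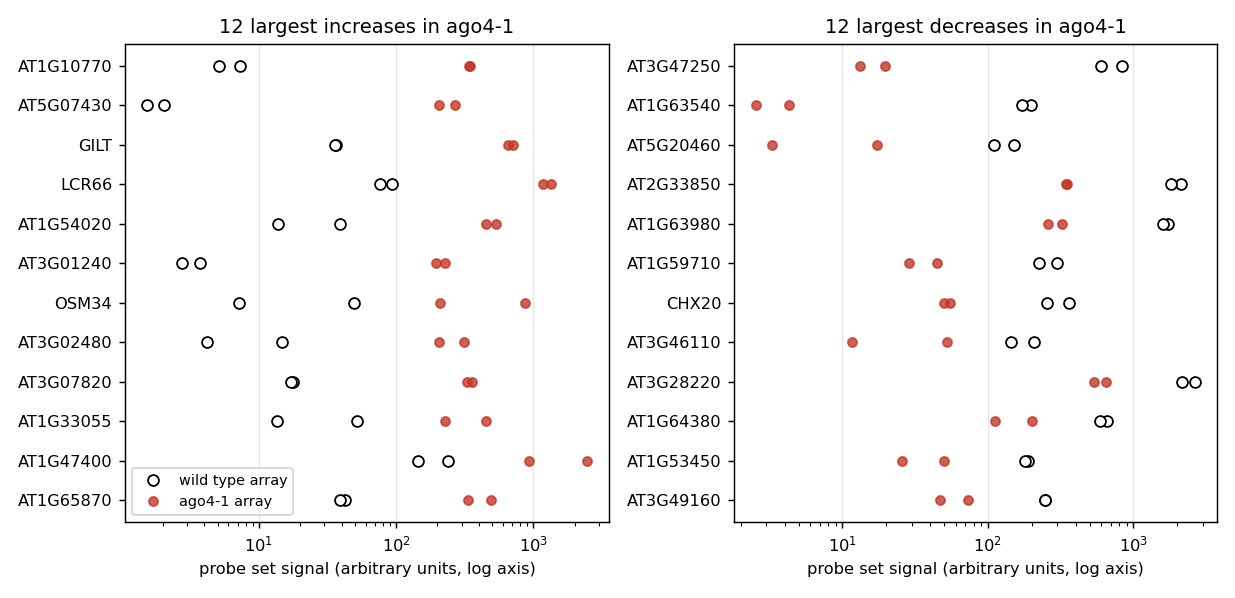
Signal on each array, on a log axis, of the 12 named genes with the largest increases and the 12 with the largest decreases in ago4-1; open black points are the 2 wild-type arrays and red points the 2 ago4-1 arrays. AT3G47250 lies at 718 in wild type and 16.4 in ago4-1 on average. The arrays of the genotypes do not overlap for any of these genes because the rule that chose them required it.

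The gene lists drawn up for this tissue and mutant held 415 genes, of which 50 were paired with a probe set by name and 39 were tested. Over all genes tested, 5 of the 39 passed, 3 higher and 2 lower in ago4-1. AGO7, an Argonaute of the trans-acting small interfering RNA pathway, rose 2.07-fold, from 116 ± 22.3 to 256 ± 15.3 (SD, n = 2 each; limma adjusted p = 0.0393). THI2.1, a thionin induced by jasmonate, rose 3.92-fold, from 223 ± 102 to 884 ± 156 (limma adjusted p = 0.00915), and the tapetum gene A9 (AT5G07230) rose 1.74-fold, from 1120 ± 107 to 1970 ± 396. DFR, which makes the precursors of anthocyanins, fell from 1322 ± 377 to 670 ± 39.1 (log2 difference -0.94), and BCAT4, of glucosinolate synthesis, fell from 11500 ± 1025 to 7642 ± 80.8 (log2 difference -0.59). All 5 calls were lost with no low-signal filter (limma adjusted p from 0.066 to 0.135), with no variance trend (0.0875 to 0.18) and without ago4-1 replicate 1 (0.0647 to 0.115). AGO7 and DFR were also lost without ago4-1 replicate 2 (0.0827 and 0.0832) or wild type replicate 1 (0.145 and 0.199), A9 without wild type replicate 1 (0.0918), BCAT4 without wild type replicate 2 (0.0873), and DFR and BCAT4 with arrays centred on their medians (0.055 and 0.0668).

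Of the 6 lists with at least 3 tested members, camera called 0, with 0 at an unadjusted p under 0.05, 0 with an estimated correlation and 0 by fry's directional test. Fry's test of change in either direction also called 0 after adjustment, its smallest unadjusted p being 0.0191 for the jasmonate and wounding list and 0.034 for the flowering time list. Of the 5 tested genes of the flowering time list 0 passed over all genes and 3 when adjusted over the list alone, with a median log2 difference of -0.561 (camera adjusted p = 0.364). Its repressor SNZ had a log2 difference of -0.82, its member GI -0.68 and its activator AGL24 0.49. Of the 3 jasmonate and wounding genes 1 passed over all genes and 2 when adjusted over the list alone, with a median of 1.182 (camera adjusted p = 0.364). JMT stood at -0.51, and the median is the value of PDF1.2, whose signals overlapped between the genotypes. Of the 3 cold, drought and abscisic acid genes 0 passed over all genes and 2 when adjusted over the list alone (median -0.811, adjusted p = 0.364), with COR15A at -0.81 and COR15B at -1.02. The 4 flavonoid and anthocyanin genes were all below 0, with a median of -0.475, 1 passing over all genes and 1 adjusted over the list alone (camera adjusted p = 0.345). In the senescence list (4 tested, median 0.265, adjusted p = 0.364) and the auxin and gibberellin list (3 tested, median 0.148, adjusted p = 0.463), 0 genes passed either way. With 1 array left out the medians moved widely, from 0.285 (without ago4-1 replicate 1) to 2.079 (without ago4-1 replicate 2) for jasmonate and wounding, from -1.281 (without wild type replicate 2) to -0.341 (without wild type replicate 1) for cold, drought and abscisic acid, and from -0.824 (without ago4-1 replicate 1) to -0.127 (without ago4-1 replicate 2) for flavonoids. The flowering time median went from -0.833 to -0.289 without those same ago4-1 arrays, replicate 2 and replicate 1. Medians turned below 0 for senescence without wild type replicate 1 or ago4-1 replicate 2 (down to -0.264) and for auxin and gibberellin without ago4-1 replicate 2 (-0.072). Jasmonate and wounding was called without wild type replicate 1 (adjusted p = 0.00243), and cold, drought and abscisic acid and flavonoids without wild type replicate 2 (adjusted p = 0.00228 and 0.00256).

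The other lists had fewer tested members and no test of the list. In the list of microRNA and post-transcriptional silencing 2 genes were tested and 1 passed both over all genes and adjusted over the list alone, SE standing at 0.09. In the anther, tapetum and pollen list 2 were tested and 1 passed either way, with AMS at -0.36. Of 2 glucosinolate synthesis genes 1 passed over all genes and 2 adjusted over the list alone, UGT74C1 (AT2G31790) standing at -0.53. The photosynthesis markers RCA and LHCB4.1 had log2 differences of -0.08 and -0.05, and the root markers EXPA18 and PYK10 -1.44 and 0.25. The single tested members of further lists were DME at -0.82 (maintenance methylation and demethylation), GRX480 at 0.52 (salicylic acid defence), HSP15.7 (AT5G37670) at 0.23 (heat shock), AUR1 at 0.26 (cell cycle) and PYE at 0.41 (phosphate and iron deficiency). The clock list held GI alone, which passed adjusted over the list alone but not over all genes. The meristem and leaf development genes PHV and YAB3 stood at 0.17 and -0.26. The lists of RNA-directed DNA methylation, genes silenced by DNA methylation, floral organ identity and seed markers had 0 tested members.

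**Figure D2:**
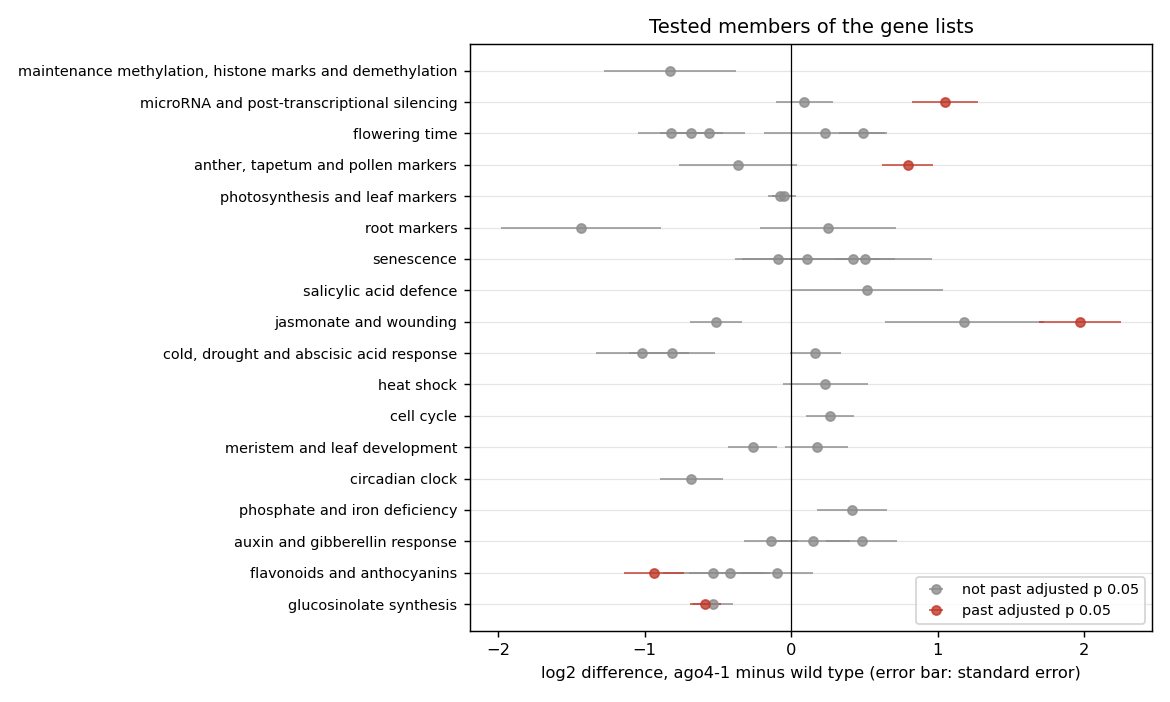
Log2 difference of ago4-1 minus wild type, with its SE, of each tested member of the gene lists; red marks the genes past an adjusted p of 0.05. AGO7, THI2.1 and A9 lie above 0 and DFR and BCAT4 below it.

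Gene families were also defined from the annotation, after the data had been obtained but before any difference was computed. Transcripts encoded in the chloroplast were lower in ago4-1, with 63 of 66 tested genes below 0 and a median log2 difference of -0.343 (camera adjusted p = 6.94e-12). With an estimated correlation that was adjusted p = 0.68. Of them rpl22, rps2, rps19 and rpoC2 passed on their own, at -0.56, -0.67, -0.50 and -0.70, and 25 passed when adjusted over the list alone. With arrays centred on their medians the calls of rpl22, rps2 and rps19 were lost (limma adjusted p from 0.0514 to 0.0989), and all 4 were lost with no low-signal filter (0.066 to 0.131), with no variance trend (0.144 to 0.211), without wild type replicate 1 (0.0584 to 0.107) and without ago4-1 replicate 1 (0.0739 to 0.0971). Without wild type replicate 2 those of rps2, rps19 and rpoC2 were lost (0.0711 to 0.134). In the same arrays a list of late-pollen loci, drawn up after the largest changes were seen, stood higher in ago4-1: of its 12 other members with a named probe set, taken with no low-signal filter, 11 were above 0. The nuclear genes taken for the photosynthetic apparatus had a median of -0.119 over 15 tested (camera adjusted p = 0.145). They were picked by symbol, so the CRR genes among them need not be parts of that apparatus. Of the family, CRR28 passed at -1.39 with a limma adjusted p of 0.0497. That call was lost with quantile normalization (0.0534), centred arrays (0.0613), a pseudocount of 1 (0.0561), no low-signal filter (0.142) and no variance trend (0.0788), and without any 1 of the 4 arrays (0.064 to 0.12).

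4 further families of the 24 were called higher in ago4-1 with the preset correlation, each at adjusted p = 0.68 with an estimated correlation. In the SWEET sugar transporters, 10 of 15 were above 0 with a median of 0.386 (adjusted p = 0.00874), and SWEET9, the nectary sugar exporter, rose from 35.5 ± 12.5 to 204 ± 26.7. The family call was lost without ago4-1 replicate 1 (adjusted p = 0.0732, median 0.124) or wild type replicate 2 (0.0532, median 0.202), and the calls of SWEET9 and LCR72 without ago4-1 replicate 1. The defensins and low-molecular-weight cysteine-rich peptides had a median of 0.4 over 7 (adjusted p = 0.00673), with LCR66 and LCR72 rising, LCR72 from 23.3 ± 2.74 to 146 ± 23.5. The median was 0.235 with no low-signal filter, 0.615 with a pseudocount of 64 and 0.271 without wild type replicate 2. The symbol rule also took in PDF1A and PDF1B, which encode peptide deformylases. Without them, a choice made after the values were seen, the median was 1.182 over 5, and 0.289 over 13 with no low-signal filter. The 1.182 is the value of PDF1.2, which is also the median of the jasmonate and wounding list. PDF1.2 was at 66.05 and 35.85 in wild type and at 259.7 and 63.45 in ago4-1, so the genotypes overlapped (limma adjusted p = 0.265). With 1 array left out the median over these 5 ran from 0.32 (without ago4-1 replicate 1) to 2.079 (without ago4-1 replicate 2). With PDF1A and PDF1B kept in, the family call was lost without ago4-1 replicate 1. It was also lost with a filter at the 50th percentile (camera adjusted p = 0.0607) and without the genes of the chromosome segments where calls gather (0.115). The RALF-like peptides had 5 of 5 above 0 with a median of 0.405 (adjusted p = 0.0152), and the autophagy genes a median of 0.387 over 8 (adjusted p = 0.0158), with ATG8H at 0.81, ATG8G at 0.62, ATG8B at 0.60 and ATG8C at 0.41. No single gene of the RALF-like and autophagy families passed over all genes. The RALF-like call was lost without either wild-type array or ago4-1 replicate 1 (adjusted p up to 0.0732), and the autophagy call without either wild-type array or ago4-1 replicate 2 (up to 0.167).

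The remaining families were not called as groups, at camera adjusted p from 0.186 to 0.974. Their called members were AGL42 at 1.01, scpl25 at 0.71, BGLU44 at -0.86, GSTU16 at 1.17, EXLA2 and EXLA1 at 1.53 and 1.02, UBC28 and UBP21 at 1.16 and -1.33, UGT76E11 and UGT72B3 at -1.43 and -1.38, and the cytochromes P450 CYP71B24 and CYP71B34 at 2.22 and -0.99. Of 989 pseudogenes in the nuclear annotation with a named probe set, the low-signal filter left 59 to be tested. Of these 2 passed, AT3G15310 at 1.67 and AT2G04460 at 2.23, with a median of -0.14 over the group. The filter on the mean of all arrays lets in a locus that is low in wild type only when it is high in ago4-1. AT2G04460 was at 9.99 and 18.7 in wild type and at 101 and 152 in ago4-1. Of the 17 called genes in families other than the chloroplast's, leaving out those with the largest changes, 14 were lost with no low-signal filter (limma adjusted p from 0.0631 to 0.16), 13 with no variance trend (0.0527 to 0.176) and 12 without ago4-1 replicate 1 (0.0575 to 0.118). Left out one at a time, the arrays ended 14 of the 17 calls, and those of UBC28, UGT76E11 and BGLU44 held. No member passed among the trichome birefringence-like genes (17 tested), tetraspanins (9), xyloglucan endotransglucosylases (3), glutamate receptor-like genes (5), WRKY transcription factors (5), nuclear RNA polymerase subunits (12), chromatin remodelling ATPases (4), vesicle transport genes (24) and tubulins (7).

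Along the chromosomes, the called genes were unevenly placed. On chromosomes 1 and 3, 5.08% of 2263 and 5.53% of 1755 tested genes were called, against 2.49% of 1245 on chromosome 2, 2.41% of 1244 on chromosome 4 and 2.54% of 2046 on chromosome 5 (Fisher's exact test, each chromosome against the rest, adjusted p from 0.000228 to 0.00796). Near AGO4 on chromosome 2, within 1000 locus steps, 12 of 608 tested genes were called (1.97%) against 313 of 7945 elsewhere (3.94%), an odds ratio of 0.491 (95% confidence interval 0.249 to 0.877, Fisher's exact test, two-sided, p = 0.0112). The genes elsewhere include chromosomes 1 and 3, where calls gather, and the 1.97% lies nearer the 2.41% to 2.54% of chromosomes 2, 4 and 5. The odds ratio therefore does not by itself show fewer calls around AGO4. These steps took in 608 of the 1245 tested genes of chromosome 2, so a short segment around AGO4 would be diluted. By the same exact test the p near AGO4 was 0.0719 with centred arrays, 0.0649 with no low-signal filter, 0.0724 with a filter at the 50th percentile and 0.185 with no variance trend. In windows of 51 neighbouring tested genes the fullest held 11 calls, where 1.94 were expected from the overall share (permutation p = 0.002, 10000 permutations). Windows with at least 10 calls formed 3 segments. They ran from AT1G56670 to AT1G61740 with 14 of 78 genes called, from AT1G63540 to AT1G64790 with 11 of 49, and from AT3G27340 to AT3G29410 with 12 of 65. LCR66, UBC28, GSTU16, CRR28, AT1G63540, AT1G63980, AT1G59710, AT1G64380 and AT3G28220 lie in these segments. AT3G47250 lies outside them but is the last called gene of a longer stretch found with windows about 3 times as wide. Together the segments held 37 calls among 192 genes (19.3%), 24 higher and 13 lower, against 288 of 8361 elsewhere (3.44%). The fullest window held 5 calls with no low-signal filter and 5 with no variance trend.

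**Figure D3:**
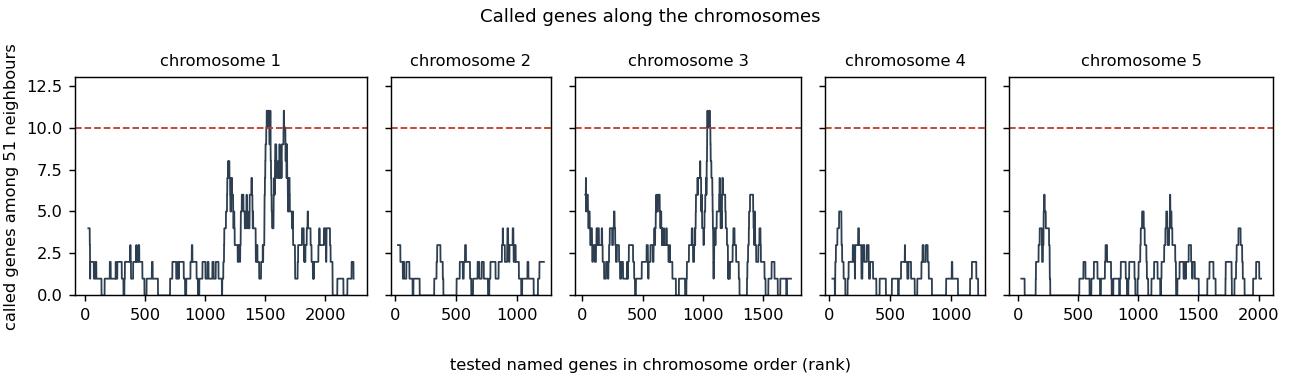
Number of called genes among 51 neighbouring tested genes, by rank along chromosomes 1 to 5; the dashed line marks 10 calls. The line is reached only on chromosomes 1 and 3, where the fullest windows hold 11 calls.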

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

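The omission of the genes in the chromosome segments was chosen after seeing the data, as were all alternatives for the families and for the position of calls. No value changed direction past its threshold. The 647 calls became 140 with no low-signal filter (136 shared), 93 with no variance trend (91 shared), 230 with a minimum difference of 1.2-fold and 1256 at an adjusted p under 0.10, and 280 to 1046 with 1 array left out. They were 683 with quantile normalization, 606 with centred arrays (61.7% higher, against 52.7%), 575 and 696 with pseudocounts of 1 and 64, 501 with a filter at the 50th percentile, 703 with robust moderation and 562 without the segments. The 0 lists called ranged from 0 to 2 with 1 array left out. The 268 probe sets apart in all pairs became 149 with a pseudocount of 64, 500 with no filter and 147 with a filter at the 50th percentile, and 429 to 700 with 1 array left out, where fewer pairs must pass. In Fisher's exact test the odds ratio near AGO4 of 0.491 was 0.603 with centred arrays (p = 0.0719), 0.176 with no filter (0.0649), 0.557 with the filter at the 50th percentile (0.0724) and 0.236 with no variance trend (0.185), and 0.364 to 0.634 with 1 array left out. The cause was not tested. Of the values for single named genes under the alternatives, 1744 kept their side of the threshold, 64 passed it newly and 124 lost it. For lists and families these were 367, 4 and 12. These counts include genes, lists and families that did not pass in the main setting and so had no call to lose. In that setting 50 named genes, 5 families and 0 lists passed, so the kept values overstate how well calls held.

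With the replicate number as a replicate block, 2409 probe sets were called, among them all 647, 1 list was called (jasmonate and wounding, adjusted p = 0.018), the autophagy family was not called (adjusted p = 0.0516), and the deviations of same-numbered arrays correlated at 0.166. With 2 pairs and no label saying that a number marks a shared batch, the numbers were not taken as pairs. The signal of AGO4 and the transposable element genes were not run under any alternative. Low signal limits the calls of genes near the floor. The filter removes those that are low on average over all 4 arrays. It keeps genes near the floor in 1 genotype and high in the other, such as AT5G07430, at 1.53 and 2.03 in wild type and 267.6 and 203.7 in ago4-1.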

Other observations

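The window scan and the tests on its segments were added after the calls were known, and the wider windows, the spread of uncalled genes in the segments, the count of calls in other splits of the arrays, the list of late-pollen loci and its test with no low-signal filter were chosen only after the result was seen. Of the late-pollen loci outside the largest changes, AT5G45880 rose from 101 ± 17.9 to 417 ± 52.7 (SD, n = 2 each; limma adjusted p = 0.00359), AT1G29140 from 30.1 ± 10.97 to 195 ± 64.5, and AT3G01270 from 79.9 ± 33.3 to 276 ± 19.9. AT3G28750, one of the 5 late-pollen loci first seen among the large changes and so left out of the test of the others, rose from 34.2 ± 13.7 to 348 ± 8.80. Among genes under the low-signal filter, BHLH101 of the iron deficiency response was at 3.43 and 2.94 in wild type and at 90.2 and 3.21 in ago4-1, and AGO8 at 5.99 and 4.52 against 25.1 and 26.6.

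The number of genes called between the genotypes was set against the other ways to part the arrays. Of the 3 splits of the 4 arrays into 2 and 2, 1 gave as many calls, the one by genotype, with 647 in limma. The other splits gave 0 calls, at most 350 probe sets at an unadjusted p under 0.05 and at most 10 at least 2-fold apart in all pairs. With 3 splits the share cannot fall under 0.05.

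Pollen-expressed genes stood among the largest increases, and a candidate explanation is more mature pollen in the ago4-1 samples. The test used 30 loci of late pollen not among those changes, listed from general knowledge after the largest changes were seen but before the values of these loci were, and not checked against a reference, so the values hold only as far as the list is right. With no low-signal filter, 11 of the 12 with a named probe set were above 0 and 1 was called, with a median log2 difference of 1.297 (95% bootstrap interval 0.981 to 2.025, camera p = 2.14e-09 and 0.0424 with an estimated correlation). The filter on the mean of all arrays keeps 8 of them, with 5 called higher, and favours loci that are high in ago4-1: only 4 of the 8 would pass on the wild-type arrays alone, with a median of 1.479 (camera p = 4.86e-06 and 0.0691 with an estimated correlation). The bootstrap interval was drawn over loci and not over arrays, so it does not measure the spread between samples. Of the 35 listed loci 3 are also on the anther, tapetum and pollen list, none of them tested, and whether the plants differed in flower number or in expression per grain was not tested.

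Called genes gathered in segments of chromosomes 1 and 3. Calls placed at random over single genes seldom filled a window as much (permutation p = 0.002). In windows about 3 times as wide the fullest held 27 calls against at most 23 in permutations (permutation p = 1e-04, the smallest they can give). These windows marked longer stretches, from AT1G55450 to AT1G67470 with 39 of 302 genes called (12.9%) and from AT3G24450 to AT3G47250 with 33 of 278 (11.9%). Elsewhere 253 of 7973 genes were called (3.17%). The permutations moved genes singly, so they do not allow for neighbours that change together. The late-pollen loci AT3G28750 and AT3G28790, for instance, were both called and lie in the chromosome 3 segment. Genes within 1000 locus steps of AGO4 were not called more often than the rest, which includes chromosomes 1 and 3 (odds ratio 0.491, upper bound 0.877). The segments lie on other chromosomes than AGO4, so a segment linked to it does not hold them. Those steps took in 608 of the 1245 tested genes of chromosome 2, so a short linked segment could be missed. Over all segments the difference of medians was -0.016 (-0.101 to 0.0949), which argues against a duplication of all segments or a deletion of all. The medians were -0.011 and -0.138 in the segments of chromosome 1 and 0.13 in that of chromosome 3. The pooled test cannot exclude copy changes that cancel between segments or cover part of one. Loss of silencing around the centromeres was not decided by its test. That test used pseudogene-rich neighbourhoods, and how far the segments lie from the centromeres was not examined. On chromosomes without a segment, genes in neighbourhoods rich in pseudogenes had an odds ratio of 1.15 (0.599 to 2.03, Fisher's exact test, p = 0.647). On chromosomes 1 and 3 it was 1.88 (1.26 to 2.72). That ratio counts the segments whose calls singled out these chromosomes, so it is not separate evidence. Segments from another parent may also account for the pattern, with 35.1% of the calls there in the rarer direction, but the spread of uncalled genes was 1.16 times that elsewhere (1.00 to 1.33), which does not decide it.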
